A study of Pilatotrama ljubarskyi with 14 samples.

How the data were processed

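RNA was extracted from mycelium of Trametes ljubarskyi grown on 5 carbon sources, and polyA RNA was sequenced in 14 libraries (3 each on maltose, cellulose, wheat straw and aspen, 2 on pine). The deposited file is a table of 878 genes with 1 column per substrate, holding log2 normalized read counts per the file headers. It carries gene numbers of the JGI MycoCosm annotation of this strain, without names. TopHat2, HTSeq and DESeq 1.5 are named per the submitters' processing notes; their settings, the scaling, the way in which libraries were combined and the choice of the genes are not given in the sources used here. Samples were grouped by the substrate in their labels, and each deposited column belongs to 1 substrate as a whole. All tests and alternatives were fixed before the data were examined, for values of single libraries, apart from those named below as chosen afterwards.

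Because the deposited log2 columns are means, the spread between libraries had to be recovered, by a procedure devised after the data were seen. The lowest values of each column fitted a mean, over the libraries of the substrate, of log2(count × factor + 1), with whole read counts and 1 factor per library. The factors were found by a search over the lowest values, where counts are small, and 131 of 131 such values were then solved by whole reads. With the factors fixed, every value up to a mean level of 13 (in pine every value) was searched for whole counts that gave the deposited number of 15 significant digits within a relative tolerance of 5e-14, or 1.8e-13 above level 10. A library was allowed to differ from the mean by up to 6 on the log2 scale up to level 8 and throughout in pine, by 4 up to level 10, by 3 up to 11, by 2 up to 12 and by 1 up to 13. A value was used only where exactly 1 set of counts fitted. The tolerances and some of these limits were widened once, before any test was run. These limits leave out genes of high level with a larger spread.

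Of 4390 values, 3953 (90.1%) were recovered, 367 were too high to search, 63 had several solutions and 7 had none. As a control, values shifted by a small amount that should have no solution were searched in the same way. Of 390 such decoys up to level 11 or in pine, 2 gave a single solution, and of 240 decoys between levels 11 and 13, 26 did, so that a value at high levels whose true counts lay outside the limits above could have been given wrong ones. Where the search of simulated values after cellulose and pine was tested, it recovered 750 and 878 of 878 genes with 0 wrong. The simulated libraries were drawn close to the mean, well inside the limits above. They therefore do not test what happens to counts that lie outside those limits. Libraries were named A, B and C within a substrate by increasing factor, and cannot be matched to the replicate numbers of the labels. The inverse of the factor gives relative depth, from 0.646 to 1.30. The reads in recovered genes ran from 705007 to 2881179 per library, over different genes in each substrate, and the total reads of a library are unknown. Counting intervals cover counting error only.

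The means and log2 differences are those of the deposited columns, and the recovered libraries give only the spread. A linear model with 1 mean per substrate over all 14 libraries was fitted with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a mean-variance trend. Where a gene had no recovered reads on a substrate, its residual degrees of freedom (1 to 9) came from the other substrates, and that substrate was assumed to vary like them; 670 of the tested genes had all 9. This left-out spread falls mostly on the highest levels. On genes with no missing value the calculation was checked to give the same adjusted p as limma's own functions. Genes with a log2 value of at least 4 in at least 2 libraries were kept, which left 867; a substrate without recovered libraries entered this rule by its deposited mean. Tests were two-sided, with Benjamini-Hochberg adjustment within each of the 8 comparisons. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Errors of log2 differences are standard errors from the fit. The recovery was done in Python 3.11.15 with numba and NumPy.

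On simulated libraries with 200 of 867 genes changed, tested for each comparison, 96% to 100% of genes with a log2 change of 2 were called, and 36% to 48% of those with a change of 1, which lies at the threshold. At most 5 of 667 unchanged genes were called.

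With no names for the gene numbers, the planned tests of gene lists (carbohydrate-active enzymes, peroxidases and other groups) were not run, and the named genes are, by the rule fixed for this case, the 2 called genes with the largest rise and the 2 with the largest fall in each comparison. Genes were ranked by fitted differences, which the 1 added inside the logarithm makes smaller for genes of few reads. The ranks of falls to few reads are therefore open, as are those of rises from few reads. Exact binomial intervals, conditional on the summed reads, are given where a group held 1 to 3 reads. Alternatives changed the filter, the pseudocount, the scaling, the variance prior, the samples in the fit and the thresholds, and left out each library in turn. Library weights and quantile normalization need a value in every library. They were run on the 670 tested genes recovered in all libraries, a restriction chosen after the data were seen. Quantile normalization gives every library the same distribution of levels, which by itself can even out the numbers of higher and lower genes, as can the median shift. The effect of libraries shared between comparisons was simulated with unchanged groups. Count models were left out of the plan, since the deposited values are logarithms. They were not run on the recovered counts either, which are missing for part of the values.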

Results

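Mycelium of the white-rot fungus Trametes ljubarskyi (strain BRFM1659), a basidiomycete of a group that breaks down both the lignin and the polysaccharides of wood, was grown for 3 days in liquid culture on 5 carbon sources. Maltose at 20 g/l, a soluble disaccharide, was the only carbon source named for 1 group. In the other 4, the medium held maltose with 15 g/l of Avicel (a microcrystalline cellulose), ground wheat straw, aspen wood or pine wood. The labels give that maltose as 2.5 g/l for cellulose, wheat straw and pine, and the amount could not be read for aspen. PolyA RNA was sequenced in 3 libraries each for maltose, cellulose, wheat straw and aspen, and in 2 for pine. The labels do not say whether the libraries of a substrate came from separate cultures. The p-values therefore rest only on the spread between libraries where it was recovered, which may be technical.

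The deposited table held 878 genes with the authors' mean log2 normalized read count for each substrate. How these genes were chosen is not given in the sources used here, so shares below are shares of this table and not of the genome. The table does not pair the gene numbers with names or functions, and genes are named here by number. Reads per library were recovered for 3953 of the 4390 values (90.1%). Where a gene has no recovered reads on a substrate, its standard error and p-value rest on its spread on other substrates. This holds for genes 1119518 and 969318 on cellulose, wheat straw and aspen, and for genes 351956, 967821, 257843 and 964653 on maltose, among others. It also holds for genes 949716, 960322, 981021 and 950280 on cellulose, gene 998652 on wheat straw and aspen, and gene 1037242 on aspen. Relative depth ran from 0.646 for a pine library to 1.30 for an aspen library. Levels are on the log2(normalized reads + 1) scale, and 867 genes were tested.

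Across the 681 genes recovered in all 14 libraries (670 of them tested), Pearson's r within a substrate ran from 0.964 to 0.993. Between substrates it ran from 0.696 to 0.950. These are correlations across genes, which are not independent replicates. The first principal component, with 59.5% of the variance, separated the maltose libraries from all others. The next, with 19.2%, placed cellulose at one end and aspen at the other. Among the deposited means, wheat straw and pine were closest (r = 0.963 across genes), and maltose and aspen were farthest apart (r = 0.671). Maltose library B had r values of 0.964 and 0.965 with the other maltose libraries, which had 0.992 with each other.

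**Figure D1:**
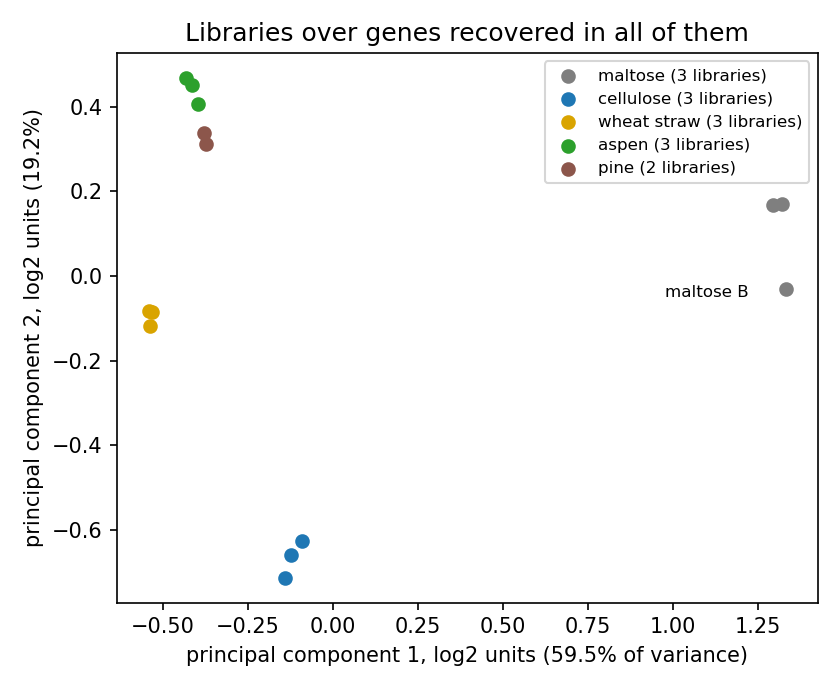
Each point is 1 library, coloured by substrate. It is placed by the first and second principal components (log2 units) over the 681 genes recovered in all 14 libraries. The 3 maltose libraries lie apart from the other 11 on the first component (59.5% of the variance), and the second (19.2%) runs from cellulose to aspen.

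Each comparison with maltose sets a solid substrate with maltose at 2.5 g/l (unread for aspen) against maltose alone at 20 g/l. The presence of the solid and the smaller amount of soluble sugar cannot be told apart. On cellulose, genes 1119518 and 969318 had the largest fitted rises. Gene 1119518 had a deposited mean of 5.70 on maltose and 17.57 on cellulose, a log2 difference of 11.86 ± 0.21 (SE; limma adjusted p = 1.53e-09). Gene 969318 went from 4.44 to 16.25, a log2 difference of 11.82 ± 0.25 (limma adjusted p = 4.61e-09). Gene 968537 fell by 6.82 on the log2 scale (SE 0.73; limma adjusted p = 1.81e-06), from 341, 342 and 562 reads in the maltose libraries to 5, 9 and 0 in the cellulose libraries. Gene 351956 fell by 6.43 (SE 0.22; limma adjusted p = 1.58e-10), from a mean of 12.74 to 6.30. The place of gene 1007871 among the largest falls is open. It had 236 reads on maltose and 3 on cellulose, a depth-scaled ratio of 0.0114 (exact 95% interval 0.00232 to 0.0336, counting error only). In all, 370 of 867 genes changed, 225 higher and 145 lower on cellulose, and 185 of them differed at least 4-fold. After a median shift of each library 214 were higher and 151 lower. Restricted to the 670 genes recovered in every library 134 were higher and 121 lower, and after quantile normalization 116 were higher and 133 lower. In each comparison the genes left out, mostly of high level, were called more often than those kept. The splits among the 670 genes therefore also reflect which genes were lost.

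**Figure D2:**
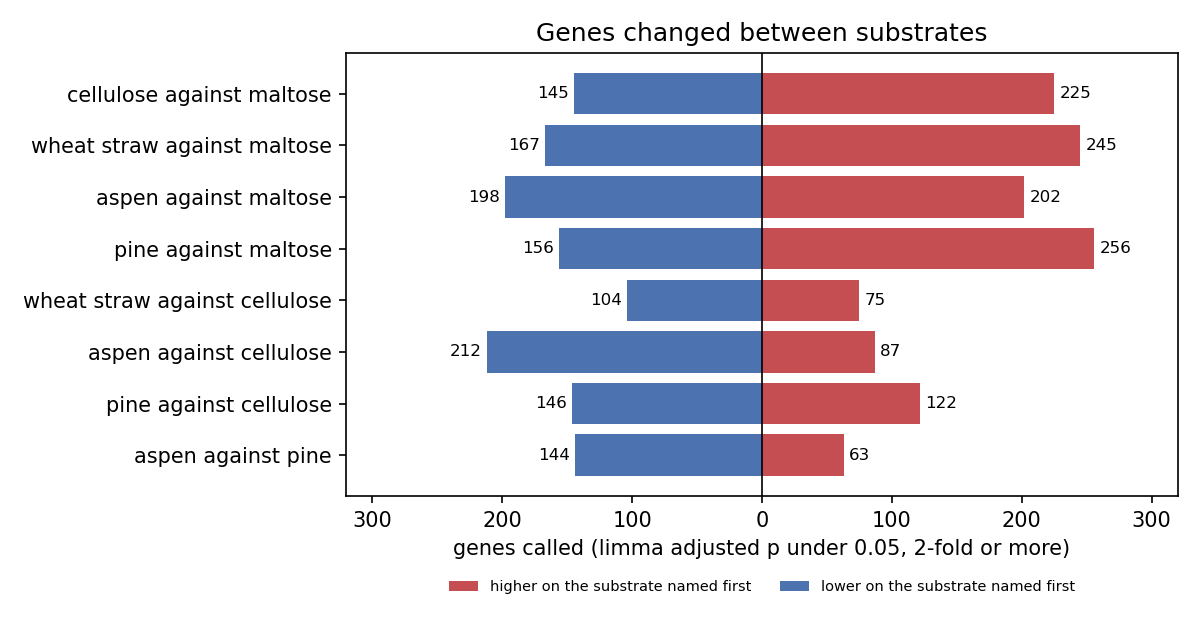
Bars count the genes called higher (right) or lower (left) on the first substrate of each comparison, out of 867 tested, by limma at an adjusted p under 0.05 and a difference of at least 2-fold. The 4 comparisons with maltose call 370 to 412 genes and the others 179 to 299. The balance of higher and lower calls depends on the scaling of the libraries; for aspen against pine, the 144 lower calls become 95 after a median shift.

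On wheat straw, the same 2 genes had the largest fitted rises against maltose. Gene 1119518 was higher by 10.12 ± 0.21 (SE; limma adjusted p = 3.54e-09) and gene 969318 by 9.97 ± 0.25 (SE; limma adjusted p = 1.06e-08). Gene 1036087 fell by 7.66 on the log2 scale (SE 0.24; limma adjusted p = 1.26e-11). Its reads were 3543, 6088 and 2963 in the maltose libraries and 19, 24 and 13 in the straw libraries. Gene 969524, with 1 read in all 3 maltose libraries together and 1966 in the straw libraries, had a depth-scaled ratio of 2022 (exact 95% interval 363 to 79915, counting error only), so its place among the largest rises is open. Gene 967821 fell by 7.36 (SE 0.50; limma adjusted p = 7.15e-08), from a mean of 13.56 to 6.20. Gene 1007871 again had an open rank among the falls. It had 236 reads on maltose and 2 on straw, a depth-scaled ratio of 0.00872 (exact 95% interval 0.00105 to 0.0318, counting error only). A total of 412 genes changed, 245 higher and 167 lower on straw, and 231 of them differed at least 4-fold. After a median shift, 231 were higher and 183 lower. With only the 670 genes recovered in every library, 149 were higher and 135 lower, and quantile normalization turned this to 134 higher and 145 lower.

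On aspen, gene 969318 rose by 10.46 ± 0.25 (SE; limma adjusted p = 8.86e-09) and gene 1119518 by 9.57 ± 0.21 (SE; limma adjusted p = 5.57e-09) relative to maltose, the largest fitted rises. The rank of gene 969524 is open here too, with a depth-scaled ratio of 1082 (exact 95% interval 194 to 42752, counting error only). Gene 257843 fell by 6.62 on the log2 scale (SE 0.49; limma adjusted p = 1.89e-07), from a mean of 12.49 to 5.87. On maltose, no whole reads within 1 of that mean (log2) fitted. Its maltose spread is therefore unknown, may be larger, and is not in this SE. Gene 351956, which also fell on cellulose, fell by 6.36 (SE 0.22; limma adjusted p = 2.58e-10). Rises and falls were nearly equal in number, with 202 genes higher and 198 lower among 400 changed. Of these, 211 differed at least 4-fold. A median shift gave 206 higher and 195 lower. In the 670 genes recovered in every library, 128 were higher and 151 lower, and 126 and 140 after quantile normalization.

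On pine, gene 1119518 rose by 8.89 ± 0.23 (SE; limma adjusted p = 2.26e-08) relative to maltose. Gene 1054011 rose by 8.42 ± 0.18 (SE; limma adjusted p = 7.44e-09), from 323, 338 and 240 reads in the maltose libraries to 101217 and 63728 in the pine libraries. These were the largest fitted rises, and the rank of gene 969524 is again open, with a depth-scaled ratio of 356 (exact 95% interval 63.1 to 14133, counting error only). Gene 964653 fell by 7.06 on the log2 scale (SE 0.56; limma adjusted p = 2.08e-06), from a mean of 14.69 to 7.63. Gene 351956 fell by 6.35 (SE 0.24; limma adjusted p = 1.59e-09), so that its mean on the 4 solid substrates lay between 6.04 and 6.39, against 12.74 on maltose. Among the falls, the rank of gene 969810 is open. It had 463 reads on maltose and 3 on pine, a depth-scaled ratio of 0.0121 (exact 95% interval 0.00249 to 0.0357, counting error only). Of 412 changed genes, 256 were higher and 156 lower on pine, and 213 differed at least 4-fold. A library's median shift was its median difference from the mean of all libraries, over the 670 genes recovered in every library. On average it was 0.20 higher for pine than for maltose. The median pine minus maltose difference over all 867 tested genes was 0.33, and the changes on pine are not corrected for either value. With the median shifts removed, 224 genes were higher and 178 lower. Over the 670 genes recovered in every library, 165 were higher and 127 lower, and quantile normalization turned this to 125 higher and 141 lower.

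**Figure D3:**
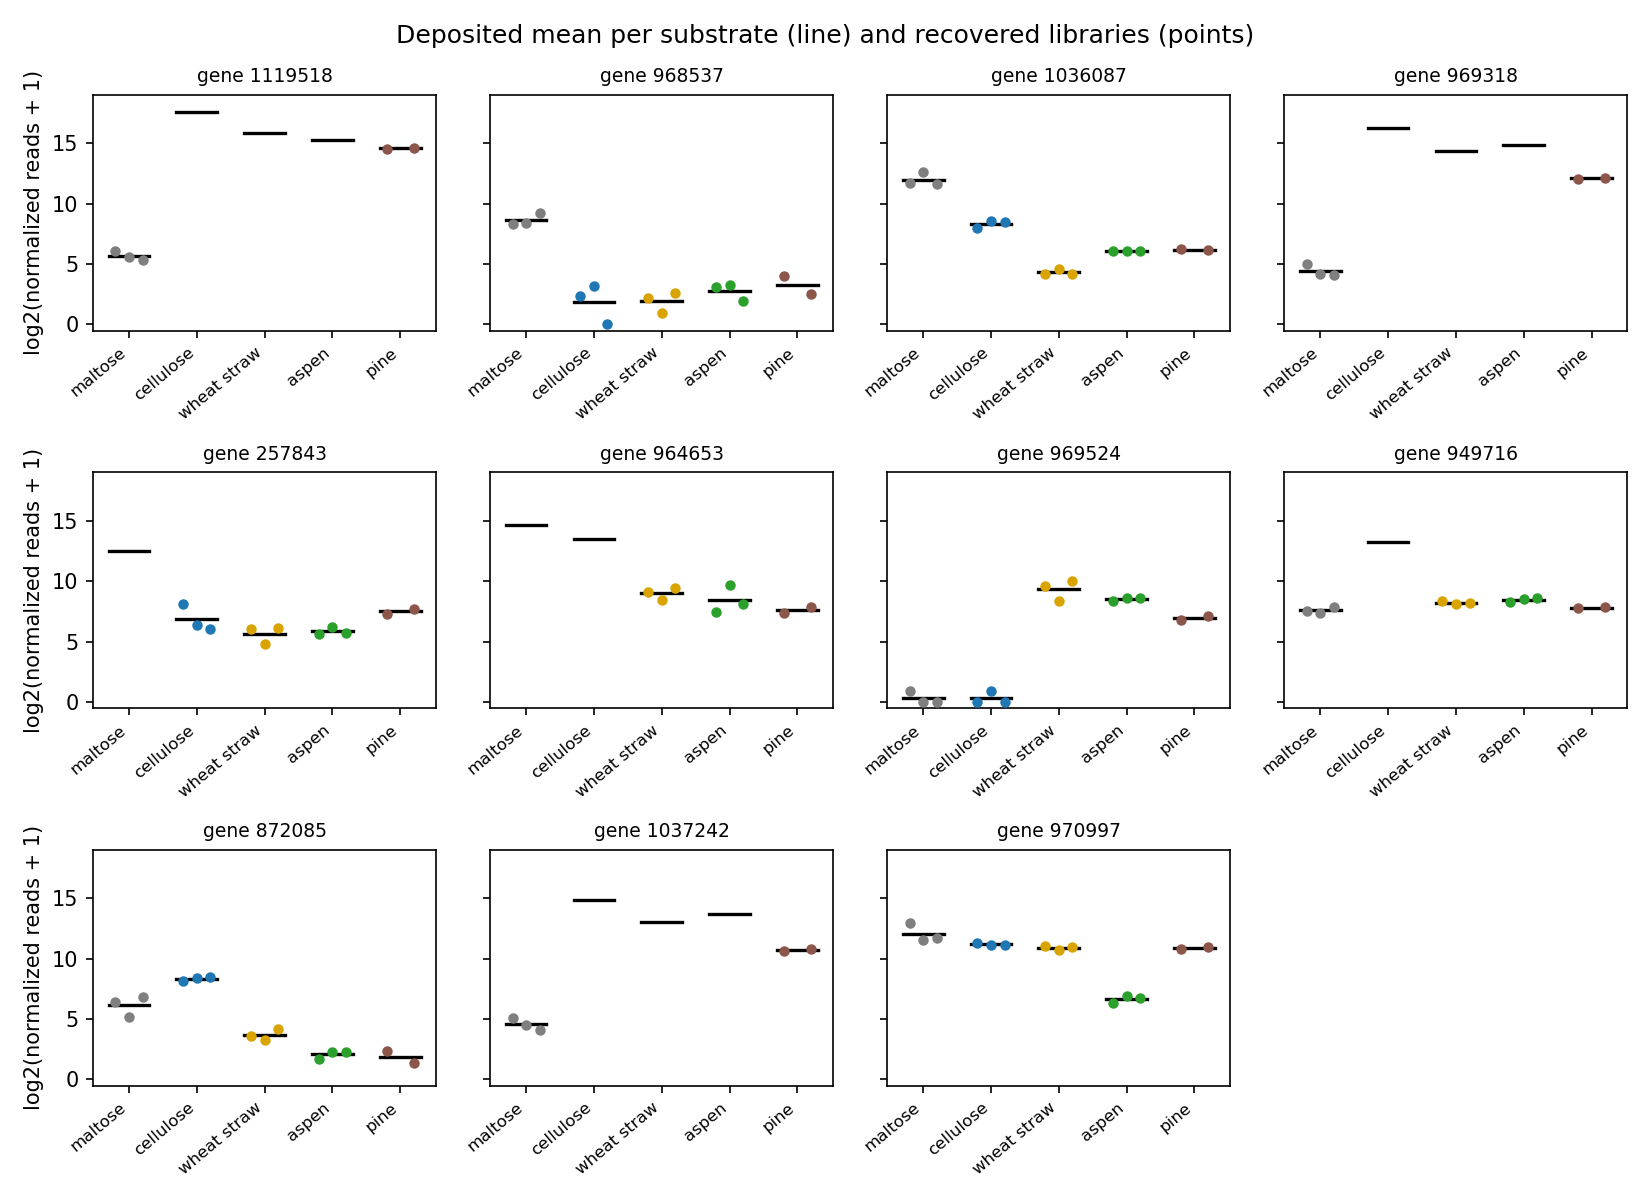
Each panel shows 1 gene, with the log2(normalized reads + 1) level on the y axis and the 5 substrates on the x axis. Lines mark the deposited means and points the recovered libraries, which are left out where reads could not be recovered; gene 1119518, for example, goes from 5.70 on maltose to 17.57 on cellulose.

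Many changes against maltose were common to the plant materials. On wheat straw, aspen and pine together, 160 genes were higher than on maltose, and 137 of these were also called higher on cellulose. Independent lists of these sizes would share 16.9 genes, a value that leaves out the shared maltose libraries. In 100 simulations of unchanged groups against those libraries the shared count had a mean of 0, but with a mean of 0.04 calls in all it could hardly differ from 0 and is no reference. The simulated differences from maltose had a mean correlation across genes of 0.47 and a mean covariance of 0.03 (log2 units squared), where the observed values were 0.93 and 4.91. The 3 maltose libraries cannot be split into parts of at least 2, and part of the overlap may come from these shared libraries. In the falling direction, 122 genes were lower on all 3 plant materials than on maltose (6.86 for independent lists). On all 4 solid substrates, 137 genes were higher and 89 lower than on maltose, where independent lists would share 4.37 and 1.15. The 4 sets of differences had a mean covariance of 4.79, and 0.03 in simulations of unchanged groups. Among the 670 genes with reads recovered in every library, 90 of the 160 genes were tested and 90 were called.

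The comparisons with cellulose set each plant material in place of Avicel, both at 15 g/l. They do not show what plant material adds to cellulose. For aspen, where the amount of maltose could not be read, a difference in soluble sugar cannot be told apart. On wheat straw, gene 969524 had the largest fitted rise. It had 838, 351 and 777 reads in the straw libraries and 1 read in all 3 cellulose libraries together. Scaled for depth, the ratio of the summed reads was 2265, with an exact 95% interval of 406 to 89492 that covers counting error only. Its fitted log2 difference of 9.02 ± 0.40 (SE; limma adjusted p = 1.68e-09) depends on the 1 added inside the logarithm. Gene 998652 rose by 5.45 ± 0.16 (SE; limma adjusted p = 7.77e-09), from a mean of 7.91 to 13.36. Gene 949716 fell by 5.07 on the log2 scale (SE 0.14; limma adjusted p = 8.48e-10), and gene 960322 fell by 4.81 (SE 0.24; limma adjusted p = 2.55e-08), from 16.06 to 11.24. Reads of genes 949716 and 960322 were not recovered on cellulose, nor those of gene 998652 on straw. Their SEs therefore leave out the spread there. In all, 179 genes changed, 75 higher and 104 lower on straw, and 67 of them differed at least 4-fold. A median shift gave 74 higher and 106 lower. Among the 670 genes recovered in every library, 106 were called, 53 higher and 53 lower, and these had also been called among all 867. Quantile normalization gave 52 higher and 55 lower.

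On aspen, gene 969524 had 415, 408 and 409 reads, 1211 times the depth-scaled level on cellulose (exact 95% interval 217 to 47875, counting error only). Its fitted log2 difference was 8.20 ± 0.40 (SE; limma adjusted p = 2.80e-09). Gene 953491 rose by 5.67 ± 0.56 (SE; limma adjusted p = 1.57e-06), from 35, 32 and 6 reads on cellulose to 1336, 998 and 864 on aspen. Gene 872085 fell by 6.26 on the log2 scale (SE 0.41; limma adjusted p = 3.49e-08), from 342, 373 and 369 reads to 3, 4 and 4. Gene 981021 fell by 5.62 (SE 0.19; limma adjusted p = 1.36e-09), from a mean of 14.88 to 9.25. The SE of gene 981021 leaves out its spread on cellulose, where its reads were not recovered. Most of the 299 changed genes were lower on aspen, 212 against 87 higher, and 110 differed at least 4-fold. After a median shift of each library 99 were higher and 195 lower. Among the 670 genes recovered in every library, 72 were higher and 126 lower, and after quantile normalization 95 were higher and 101 lower.

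On pine, gene 969524 had 102 and 88 reads, 399 times the depth-scaled level on cellulose (exact 95% interval 70.7 to 15826, counting error only), with a fitted log2 difference of 6.62 ± 0.45 (SE; limma adjusted p = 5.78e-08). Gene 953491 rose by 6.11 ± 0.62 (SE; limma adjusted p = 3.04e-06), to 1158 and 843 reads. Gene 872085 fell by 6.48 on the log2 scale (SE 0.46; limma adjusted p = 9.09e-08), to 4 and 1 reads. Gene 950280 fell by 6.39 (SE 0.19; limma adjusted p = 4.39e-10), from a mean of 15.96 to 9.58. The SE of gene 950280 leaves out its spread on cellulose, where its reads were not recovered. Of 268 changed genes, 122 were higher and 146 lower on pine, and 119 differed at least 4-fold. The median shift of the pine libraries was on average 0.14 above that of the cellulose libraries, over the genes recovered in every library. Over all 867 tested genes the median pine minus cellulose difference was 0.08. With the median shifts removed, 99 genes were higher and 170 lower. Among the 670 genes recovered in every library, 175 were called, 92 higher and 83 lower, and quantile normalization gave 85 higher and 91 lower.

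Across the 3 plant materials, 34 genes were higher than on cellulose in every comparison and 78 were lower, where independent lists would share 1.06 and 4.28. Simulations of unchanged groups against the shared cellulose libraries shared 0 genes, with 0.08 calls in all, and so give no reference count. They gave a mean covariance of the differences of 0.03, against 1.33 observed. The 3 cellulose libraries cannot be split either, and part of the overlap may come from them. Genes higher on wheat straw, aspen and pine than on both maltose and cellulose numbered 26. Among them was 969524, which had 1 read in the 3 maltose libraries. This count fell to 16 without wheat straw library A, B or C, to 16 without aspen library A and to 17 without aspen library B or C. Leaving out a library drops the genes without recovered reads on that substrate, and only 16 of the 26 were tested in each of these fits.

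Aspen, a hardwood, and pine, a softwood, were compared directly. Gene 1037242 was higher on aspen by 3.00 ± 0.27 (SE; limma adjusted p = 8.89e-05), with a mean of 13.73 against 10.73. Gene 1052161, at much lower levels, was also higher by 3.00 ± 0.40 (SE; limma adjusted p = 4.79e-05), with 61, 56 and 78 reads on aspen and 6 and 4 on pine. Gene 970997 was lower on aspen and fell by 4.21 on the log2 scale (SE 0.31; limma adjusted p = 2.72e-06). It had 104, 127 and 111 reads on aspen against 1691 and 1276 on pine, and its mean on the other 3 substrates was between 10.92 and 12.06. Gene 377338 fell by 3.06 (SE 0.33; limma adjusted p = 9.60e-06), from a mean of 10.64 on pine to 7.58 on aspen. Of 207 changed genes, 63 were higher and 144 lower on aspen, and 33 differed at least 4-fold.

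The excess of lower genes shrank under other scalings. The median shift of the aspen libraries relative to the pine libraries was -0.22 on the log2 scale, over the genes recovered in every library. Over all 867 tested genes the median aspen minus pine difference was -0.23. After each library was shifted by its median, 87 genes were higher and 95 lower. Among the 670 genes recovered in every library, the split was 34 higher and 93 lower, and quantile normalization gave 56 higher and 58 lower. Genes 1052161, 970997 and 377338 were called in the same direction under the median shift and under quantile normalization; gene 1037242 was called under the median shift and could not enter the quantile normalization.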

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

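The restriction to genes recovered in all 14 libraries (alone, with library weights or with quantile normalization) and the bounds for other splits were chosen after the data were seen. All 32 named results (21 genes) kept direction and call in all 379 alternative values computed. Picked as the largest changes, they could hardly fail, so this tests little. Over 7 alternatives (filter, pseudocount of 16, median shift, variance prior, only the 2 groups compared), all counts stayed within 1.5 times.

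The thresholds moved the counts by construction. At 4-fold they were 185, 231, 211 and 213 for cellulose, straw, aspen and pine against maltose, 67, 110 and 119 for straw, aspen and pine against cellulose and 33 for aspen against pine. The genes raised on the 3 plant materials against maltose numbered 99, and those also higher than on cellulose 12. With the adjusted p alone the counts were, in the same order, 603, 634, 641, 628, 324, 554, 486, 448, 244 and 41.

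Testing only the 670 genes recovered in every library dropped mostly high-level, more often called genes and lowered the counts. They were 106, 198 and 175 for straw, aspen and pine against cellulose, 124 for aspen against pine, 90 for genes raised on the 3 plant materials and 16 for those also higher than on cellulose. The calls were those made among all 867 genes, except 3 lost for aspen against pine. With library weights the counts were 110, 199 and 168 against cellulose, 83 raised on the 3 plant materials and 17 also higher than on cellulose. With quantile normalization they were 266 for aspen and 266 for pine against maltose, 107, 196 and 176 against cellulose, 114 for aspen against pine and 80 raised on the 3 plant materials. Of the 127 aspen against pine calls among these genes, quantile normalization kept 89; the cause was not tested.

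Leaving out 1 library gave 16 to 28 genes higher on the 3 plant materials than on maltose and cellulose. Dropping a straw or aspen library removes genes not recovered there. Over the 45 fits of a comparison without 1 library, 11610 of 12358 calls made among the same genes remained and 0 reversed. The smallest share was 77.2%, for aspen against pine without pine library B, where the lone pine library is assumed to vary like the other groups. Without maltose library B, 346, 380, 348 and 367 genes were called for cellulose, straw, aspen and pine against maltose, where 338, 372, 353 and 373 of the same 777 genes had been called with it.

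With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Counting each real split as 1 of the 10 with as large a result, and only genes recovered on both substrates, cellulose against maltose called 270 genes and the highest other split 3. The values were 321 and 0 for straw against maltose, 314 and 0 for aspen against maltose, 112 and 0 for straw against cellulose and 207 and 3 for aspen against cellulose. No paired analysis was possible because the deposited columns carry no replicate numbers and the recovered libraries cannot be matched to those of the labels. The gene list tests were not run for want of names. Depth limits the genes of few reads, and recovery the spread known at the highest levels.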

Other observations

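The counts and genes of the first and second paragraphs were chosen after their values were seen, as were the tests of scaling for aspen against pine and of a move towards the solid-substrate profile. Among the 878 genes of the table, the gene with the highest level differed between maltose, cellulose, aspen and pine. Levels here are normalized reads without a correction for gene length. Of the linear sum over the 878 genes, back-transformed from the deposited means, the 10 highest genes held from 19.7% on wheat straw to 26.7% on aspen, with 22.5% on maltose and 26.2% on cellulose. The highest was gene 965600 on maltose (16.68), gene 54315 on cellulose (18.19) and wheat straw (16.76), gene 1054873 on aspen (16.85) and gene 1048925 on pine (17.11). Gene 54315 alone held 6.97% of that sum on cellulose and 3.39% on wheat straw. Maltose was the substrate of the lowest level for 336 of the 878 genes and of the highest for 242. Cellulose was the highest for 177, wheat straw for 125, aspen for 124 and pine for 210.

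A set of 51 genes was called higher on cellulose than on maltose and then lower on each of wheat straw, aspen and pine than on cellulose. All these calls use the same cellulose libraries, so an error in the cellulose mean alone could give the pattern. Many of the set, among them genes 949716, 960322, 981021 and 950280, had no recovered reads on cellulose. Their spread there is unknown. In the opposite sense, 13 genes were higher on all 3 plant materials than on cellulose and were not called between cellulose and maltose, where a missed call does not show equal levels. Of 579 genes that changed in at least 1 of the 4 comparisons with maltose, 17 were higher on one solid substrate and lower on another. These comparisons share the maltose libraries, which alone gave a correlation of the differences of 0.47 in simulations of unchanged groups. The mean covariance there was only 0.03, against 4.79 observed. Gene 970997 is a case in which aspen stood apart from the other 4 substrates, at 6.66 against 10.87 to 12.06.

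Maltose library B stood apart from libraries A and C over the 788 genes recovered on maltose. A scaling factor was not weighed, since it hardly changes a correlation of log values. Counting noise at low levels is argued against, since above level 8 the spread across genes of B minus A (SD 0.673), medians removed, was 3.25 times that of C minus A (bootstrap 95% interval over genes 2.70 to 3.94; 437 genes). A culture partly moved towards the solid substrates would give a positive correlation across genes of B minus A with cellulose minus C; r was 0.0805 (0.00833 to 0.157), with wheat straw, aspen and pine in place of cellulose it was 0.103, -0.0132 and 0.0682, and the 95% intervals of all 4 end below 0.2, the value set for such a move. A minus C with cellulose minus B gave 0.119, and on the first principal component B (1.33) lay no nearer to the solid substrates than A (1.30) or C (1.32). On the second component, B (-0.03) lay nearer than A (0.17) or C (0.17) to the cellulose libraries (-0.63 to -0.71). The r of B with cellulose library C was 0.777, against 0.758 for A and 0.754 for C. It was also higher with the other cellulose libraries and with every wheat straw library, but lower with every aspen library. With the pine libraries it lay between those of A and C. Such a move is thus not shown as the main difference. A part towards cellulose or wheat straw stays open. The intervals of cellulose, wheat straw and pine also reach above 0.1, to 0.157, 0.183 and 0.151. A difference between cultures or in RNA handling may account for the distance of library B and was not tested.

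The excess of lower calls on aspen against pine was weighed against a scaling difference between these libraries. A uniform scaling difference shifts every gene alike, but the median of aspen minus pine was -0.11 (-0.18 to -0.0049) in the 289 genes of lowest mean level, -0.18 (-0.30 to -0.08) in the 289 of middle level and -0.51 (-0.64 to -0.41) in the 289 of highest level (bootstrap 95% intervals over genes). The largest difference between these medians, 0.401, argues against uniform scaling as the whole cause. A part for scaling stays open; the nearly even split after a median shift does not bear on it, because centring evens the split whatever the origin of the offset. The wood itself also stays open and was not tested, as does the soluble sugar, since the amount of maltose with aspen is unknown here. Pine had only 2 libraries.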
